A study of Drosophila melanogaster with 164 samples.

How the data were processed

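The libraries were polyA-selected, stranded mRNA libraries of whole Drosophila melanogaster from inbred lines of the Drosophila Genetic Reference Panel, a set of wild-derived lines with sequenced genomes. Larvae and adults of 41 lines were sampled with 2 biological replicates per line and stage, which gave 82 larval and 82 adult libraries. The deposited values are raw counts per gene in 1 table of 7414 genes by 164 libraries, and replicates were not pooled in it. FastQC, Trimmomatic and STAR and the genome builds BDGP6 and dm6 are named, without versions, per the submitters' processing notes. Every gene of the table had at least 11 counts in every library, so genes silent at either stage or in any 1 line are absent. Column totals cover the retained genes alone. Gene names and positions were taken from the Ensembl BDGP6 annotation, in which 7349 of the identifiers were found, 7322 of them protein coding, and 65 were not found.

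Groups, lines and replicates were taken from the sample labels. The comparisons, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Alternatives added later were pools as replicates, all 164 columns, a set without 3 larval libraries, roX1 as a covariate, a stricter CPM filter for line variation, a fold test in DESeq2, r without the most influential line, Spearman's rho in the matched lists and in the closing tests, and r within clusters of lines. The larval columns labelled DGRP787 replicate 1 and DGRP491 replicate 2 held identical counts, so both were left out, which left 162 libraries, 80 larval and 82 adult. The plan had named all 164 libraries.

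Counts were normalised with TMM factors in edgeR 4.0.16 under R 4.3.3. A filter of 1 CPM (a count scaled to a common library total) in at least 41 libraries of a stage removed no gene, so a fit without it would be the same fit. Stage differences were tested with the edgeR quasi-likelihood F test with line as a block, and differences of at least 2-fold with glmTreat. Line differences within each stage were tested over all 40 line coefficients, and the line-by-stage interaction over 40 coefficients, with the same F test. The Benjamini-Hochberg adjustment was applied to each family of tests, with a threshold of 0.05. Gene lists were compared between stages with camera in limma 3.58.1 with a preset correlation of 0.01 and again with an estimated correlation. CPM values printed beside fold changes are of the total count, before the TMM factors, while fold changes include the factors.

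For work on line means, log2 CPM with a prior count of 2 was averaged over the replicates of each line. Broad-sense heritability was the intraclass correlation of replicates within lines, that is, the share of the variance of 1 library that lies between lines. Pearson's r between larval and adult line means was tested for each of the 7414 genes with 100000 two-sided permutations of the lines, whose smallest p is 1e-05. The genetic correlation was the covariance of line means across stages divided by the root of the product of the among-line variances. Medians over genes carry 95% bootstrap intervals from 2000 resamples of the lines, and errors of single genes are jackknife SEs over lines. The median r was also set against 1000 joint permutations of the lines. For each gene list, the median r was compared with that of all other genes and with 10000 random lists matched on expression level and on heritability at both stages, drawn from the 50 nearest genes of each member. These steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.

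Of 34 lists, 26 had at least 5 members in the table and were tested, and 8 had too few. The lists are name patterns or textbook members, and 4 genes that matched a pattern by spelling alone were dropped. Of these, the cyclophilins Cyp1 and Cyp40 were dropped from the cytochrome P450 list after the correlations had been seen.

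Named genes followed a rule. For stage, these were the 10 genes with the largest fold change in each direction among those past the threshold, with a mean of at least 10 CPM in the higher stage and the same direction in all 41 lines. For line differences, they were the 8 genes with the highest heritability in each stage at a mean of at least 10 CPM. Across stages, among genes with line variation at both stages and at least 5 CPM, they were the 10 with the highest r and the 5 with the lowest. The 8 with r nearest 0 among those with heritability of at least 0.6 at both stages and an interaction were added. In each list the 3 members with the highest mean CPM and members already named were taken, and roX1 was taken for sex composition. For every named gene, lines were grouped by single linkage on the larval and adult means, with each axis scaled to its range and a linking distance of 0.15. Within each cluster of at least 6 lines r was computed, with the Benjamini-Hochberg adjustment over 153 such relations. The clusters were drawn from the same means that were then correlated. Permutation p-values within a cluster take no account of that choice and only describe the cluster.

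The identity of the larval columns was checked with 554 genes whose adult heritability was at least 0.75, by correlating each column with the adult mean of every line. Tests were also tested on simulated data. Simulated stage differences of 1.25-fold were recovered in 100% of 100 genes. Simulated line differences with an SD of 0.25 log2 were recovered in 81% of genes in larvae and 87% in adults. False calls were 3.38% of calls for stage, 4.74% for lines in larvae and 4.59% for lines in adults. For the line-by-stage interaction, 100% of 200 simulated genes were recovered, with 15 false calls, 6.98% of calls and above the threshold. Simulated genetic correlations of 0, 0.5 and 1 at a heritability of 0.6 gave median estimates of 0.0014, 0.521 and 1.02, and 0.186%, 22.5% and 99.5% of the genes were called as correlated. The median heritability of the real genes was lower, at 0.287 in larvae and 0.390 in adults. Recovery at such values was not simulated.

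Alternatives covered DESeq2 1.42.0 size factors, the DESeq2 Wald test, limma-trend, TMM within each stage, a prior count of 0.5, pool number as a factor, a replicate block, each replicate left out, Spearman's rho, a mean CPM of at least 5, line variation past an adjusted p of 0.001, and genes variable at both stages only. The planned sex covariate for adults needs yolk and chorion genes, none of which is in the table. Line tests without 1 replicate have no residual degrees of freedom and were not run. Larvae fell into 12 pools and adults into 7 others, so pool could not be a term beside stage, and pool means served as replicates in limma-trend instead.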

Results

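RNA was sequenced from whole feeding third-instar larvae and from whole adults of the same 41 inbred lines, each with 2 replicates per stage. The labels gave no sex. Total counts per library in the table ranged from 2407244 to 26429404 in larvae, with a median of 10845004, and from 2748964 to 20421026 in adults, with a median of 8670311. The most abundant gene took a median of 4.70% of the counts in larvae and 5.51% in adults. Replicates of a line differed by more than counting error: the lowest chi-square per degree of freedom between a pair of replicates was 8.56, and the median was 63.2.

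Genes with strong line differences in adults tied larval columns to their lines. Over 554 such genes, 78 of 82 larval columns correlated most with the adults of the line on their label, with a median r of 0.480 across genes, which are not independent replicates. Another line ranked first for 4 columns, whose r with their own line was at most 0.034. The column labelled DGRP787 replicate 1 was identical to that of DGRP491 replicate 2 and matched the adults of DGRP491 with an r of 0.599, and both were left out. The libraries labelled DGRP882, DGRP897 and DGRP911 replicate 2 matched the adults of DGRP911 (r 0.481), DGRP882 (r 0.621) and DGRP897 (r 0.394). The 3 matches form a closed exchange among these lines, as an exchange of labels would give, and the extraction numbers are 88, 86 and 87. Between the larval replicates of a line, r was 0.021 for DGRP882, -0.091 for DGRP897 and 0.262 for DGRP911. The median over 39 lines was 0.417. Replicate r was also low in some lines whose larval columns both matched their own adults, such as DGRP367 (-0.089) and DGRP142 (0.0003). It therefore does not single out the libraries that matched other lines. These 3 libraries were kept under their labels, so the main larval and cross-stage values include them, and a set without them served as an alternative.

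**Figure D1:**
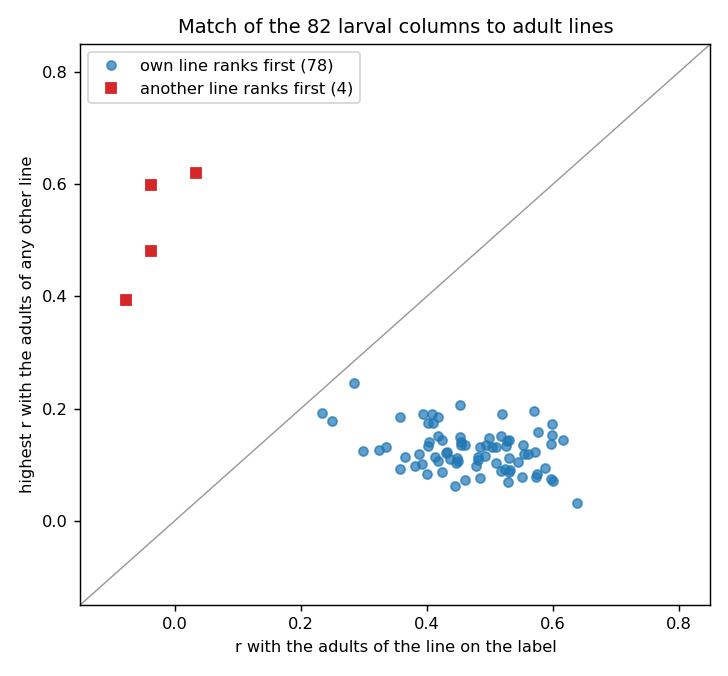
Each point is 1 of the 82 larval columns, with its correlation across 554 genes to the adults of the line on its label on the x axis and its highest correlation to the adults of any other line on the y axis. The 78 columns below the diagonal match their own line, and 4 columns lie above it with an own-line r of at most 0.034.

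The stage comparison addressed how far expression differs before and after metamorphosis among genes expressed at both stages. Cyp4g1, the P450 that makes cuticular hydrocarbons in oenocytes, stood at 247 ± 124 CPM in larvae (SD, n = 80) and 30436 ± 5616.5 CPM in adults (SD, n = 82), a log2 fold change of 6.78 ± 0.11 (SE) with an adjusted p of 7.8e-94 by the edgeR test with the Benjamini-Hochberg adjustment. Est-6, an esterase of the male ejaculatory duct, was higher in adults by 6.05 ± 0.12 on the log2 scale, and the fatty acid synthase gene FASN2 by 5.15 ± 0.10. In larvae, Ag5r2, which encodes a secreted antigen 5-related protein, stood at 5424.5 ± 2273 CPM against 38.7 ± 20.0 in adults, a log2 fold change of -7.43 ± 0.12 with an adjusted p of 1.6e-92. The peritrophic matrix genes Peritrophin-15b and Peritrophin-15a had log2 fold changes of -6.67 ± 0.13 and -5.59 ± 0.12, and the midgut serine protease Jon65Ai had -5.41 ± 0.15. Each of these genes changed in the same direction in all 41 lines.

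Among 7414 genes, 3332 were higher in adults and 3545 in larvae, and 537 did not pass. At least a 2-fold difference was found for 1110 genes in adults and 864 in larvae, and 3305 genes moved in the same direction in all 41 lines. The median absolute log2 fold change was 0.63. The other genes with the largest changes were CG7910, Ugt50B3, Cyp312a1, CG4836, CG32436, CG11147 and Gpdh3 in adults, with log2 fold changes from 4.47 to 5.81. In larvae they were Obp99b, CG7298, Fst, CG10182, CG9682 and lncRNA:CR44138, from -6.84 to -4.95. Ugt50B3 spans 20 genes on its own strand, whose reads its count might hold. Cyp4g1 (FBgn0010019) lies on chromosome X at 467057 to 469335 of the BDGP6 build, and Ag5r2 (FBgn0020508) on X at 14782962 to 14784052. Larvae and adults were in separate sequencing pools, so pools were also taken as replicates: between 12 larval and 7 adult pools, 6618 genes passed in limma-trend, 6607 of them also by library, and for 5215 genes the pool means of the stages did not overlap.

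Most genes of the synaptic, phototransduction and testis lists that were in the table were higher in adults. The table held 23 of the 30 genes that the synaptic list takes from the reference names. It held 11 of 32 for phototransduction and 8 of 39 for testis, so these lists cover only part of each set. In the synaptic list, 22 of 23 members were higher in adults and 1 in larvae, and all 23 passed adjusted over the list alone. Among these were the fusion-clamp gene cpx (3.84 ± 0.07), the vesicle-priming gene unc-13 (2.54 ± 0.07) and the sodium pump gene Atpalpha (2.05 ± 0.04). The list had an adjusted p of 1.3e-08 with the preset correlation (camera) and an adjusted p = 0.372 with an estimated correlation. Of 11 phototransduction genes, 9 were higher in adults and 2 in larvae (11 adjusted over the list alone), with norpA, the phospholipase C of the visual cascade, at 3.93 ± 0.06. That list had an adjusted p of 0.0042, and adjusted p = 0.372 with an estimated correlation. All 8 testis genes were higher in adults (8 adjusted over the list alone), among them the sperm leucyl aminopeptidases S-Lap1 (4.17 ± 0.14), loopin-1 (4.24 ± 0.13) and S-Lap7 (4.27 ± 0.14). Another of the 8, alphaTub84D, encodes a widely expressed tubulin. The testis list had an adjusted p of 8.0e-04, and adjusted p = 0.372 with an estimated correlation.

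Most genes of the ribosome, translation, proteasome and DNA replication lists were higher in feeding larvae. Among cytoplasmic ribosomal protein genes, 82 of 83 were higher in larvae and 1 in adults (83 adjusted over the list alone), with a median log2 fold change of -1.24 and RpL5 at -1.08 ± 0.03. The list had an adjusted p of 6.2e-17 with the preset correlation and adjusted p = 0.372 with an estimated correlation. Mitochondrial ribosomal protein genes had a median of -0.48, with 68 of 71 higher in larvae, 2 in adults and 1 not passing (70 adjusted over the list alone). Their adjusted p was 7.0e-06, and adjusted p = 0.540 with an estimated correlation. Translation factor genes were higher in larvae for 35 of 44, in adults for 8, and 1 did not pass (43 adjusted over the list alone), with the elongation factor gene eEF1alpha1 at -0.83 ± 0.05. That list had an adjusted p of 0.0062, and adjusted p = 0.372 with an estimated correlation. Of 32 proteasome genes, 29 were higher in larvae, 2 in adults and 1 did not pass (31 adjusted over the list alone), with Prosbeta5, a catalytic subunit, at -0.72 ± 0.03, and 1 member changed sign with DESeq2 size factors. Its adjusted p was 1.7e-04, and adjusted p = 0.540 with an estimated correlation. DNA replication and cell cycle genes were higher in larvae for 25 of 31, in adults for 5, and 1 did not pass (30 adjusted over the list alone), with the topoisomerase gene Top2 at -0.88 ± 0.04 and the mitotic kinase gene polo at 0.29 ± 0.05. That list had an adjusted p of 0.0022, and adjusted p = 0.540 with an estimated correlation.

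Of 19 digestive serine proteases, 17 were higher in larvae, 1 in adults and 1 did not pass (18 adjusted over the list alone), with Jon65Aiv at 19456 CPM in larvae and 2209.8 in adults, a log2 fold change of -3.46 ± 0.10. The list had an adjusted p of 6.4e-05, and adjusted p = 0.372 with an estimated correlation. Of 10 carbohydrate digestion genes, 8 were higher in adults and 2 in larvae (10 adjusted over the list alone), with the maltase genes Mal-A1 at 3.47 ± 0.14 and Mal-A6 at 2.55 ± 0.11, although this list did not pass (adjusted p 0.202). Muscle sarcomere genes went both ways, with 15 of 22 higher in larvae and 5 in adults (adjusted p 0.0568). Of 21 insulin and TOR signalling genes, 16 were higher in adults, 4 in larvae and 1 did not pass, with a median log2 fold change of 0.37 (adjusted p 0.063). The remaining lists did not pass either, with adjusted p between 0.0586 for peritrophins and mucins and 0.812 for ecdysone and juvenile hormone genes. For that last list the median log2 fold change was 0.01 and the mean -0.32, and for fat body metabolism genes they were -0.09 and 0.21, with the test following the mean in both. With an estimated correlation, 0 lists passed the Benjamini-Hochberg adjustment in camera, and 3 had an unadjusted p under 0.05. roX1, an RNA of the male dosage compensation complex, stood at 224 ± 105 CPM in larvae and 855.5 ± 202 in adults (1.76 ± 0.08 on the log2 scale, higher in adults in all 41 lines).

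**Figure D2:**
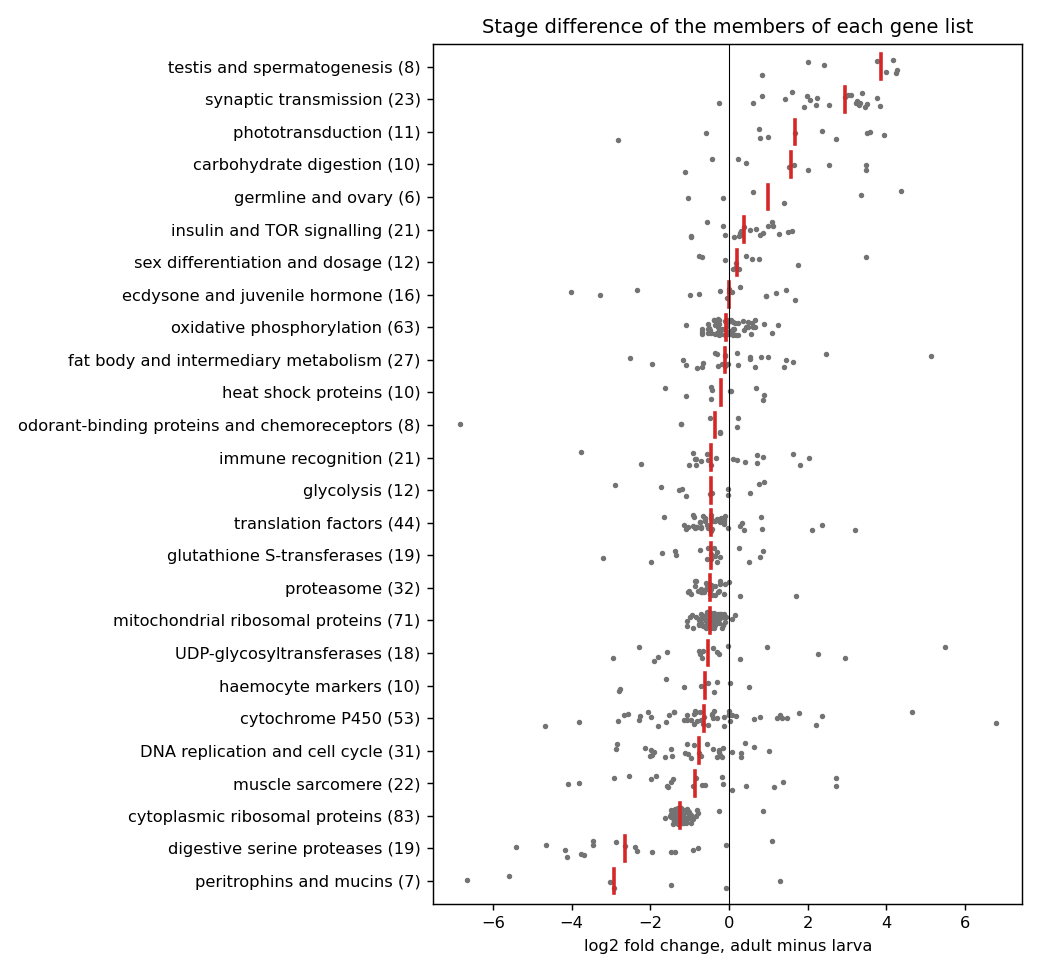
Points are the genes of each of 26 lists, with the number of members in brackets, at their log2 fold change between adults and larvae, and bars mark list medians. Medians run from -2.93 for peritrophins and mucins to 3.88 for testis genes.

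The next comparison asked which genes differ between lines within a stage. In larvae the highest heritability was that of Sans, which encodes a scaffold protein of the Usher complex, at 0.976 ± 0.013 (SE over 41 lines). In adults it was that of Jon74E, a Jonah family serine protease, at 0.983 ± 0.007, and its line means spanned 587-fold in larvae and 519.7-fold in adults. The adenylate kinase gene Ak3 was among the highest at both stages, with 0.930 ± 0.177 in larvae and 0.951 ± 0.255 in adults, where DGRP879 stood apart from the other lines. In larvae the next were CG2493, CG42846, CG10646, the cathepsin gene CtsK1, the argininosuccinate synthase gene Ass and the autophagy gene Atg16, from 0.923 to 0.947. In each of these a few lines stood apart in larvae: CG2493 was low in DGRP149, at 2.20 log2 CPM, and its other 40 lines spanned 2.30-fold. CG10646 was high in DGRP158, CtsK1 low in DGRP832, Ass low in DGRP486 and DGRP796, Atg16 high in DGRP181 and DGRP427, and CG42846 low in DGRP380, DGRP535, DGRP787 and DGRP804. In adults the next were Ugt35A1, Cyp6w1, Acsf2, CG17036, Dip-C and CG1635, from 0.944 to 0.966. Of these, Ugt35A1 was lowest in DGRP181, Cyp6w1 in DGRP370 and Acsf2 in DGRP897, Dip-C was low in DGRP805, DGRP879 and DGRP882, and CG1635 in DGRP181 and DGRP783.

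Differences between lines passed the edgeR test for 3453 genes in larvae and 5075 in adults after the Benjamini-Hochberg adjustment. Both lists shared 2849 genes, against 2364 expected from independent lists, an odds ratio of 3.68 across genes, which are not independent replicates. The median heritability was 0.287 in larvae (95% interval 0.197 to 0.356) and 0.390 in adults (0.316 to 0.443). The adult minus larva difference was 0.104, with an interval from -0.0019 to 0.214 that includes 0. Replicates varied more in larvae, with a median SD of 0.26 log2 against 0.20 in adults, while the median SD between lines was 0.16 and 0.15. With pool number as a factor, 2288 genes passed in larvae.

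The central comparison was whether lines kept their rank in expression from larva to adult, which bears on the genetic independence of stages that the series names. The retinol dehydrogenase gene Rdh1 (chromosome 2R, 7665828 to 7667343) fell into a group of 26 lines with high levels at both stages and one of 12 with low levels at both. Within the 26 lines r was 0.573 (permutation p 0.0021, adjusted p 0.019; rho 0.627, p 7.9e-04) and 0.446 without the 2 lines farthest from the larval median, and within the 12 lines it was 0.759 (permutation p 0.0029, adjusted p 0.022; rho 0.797, p 0.0029) and 0.756. With pool differences removed these were 0.290 and 0.323. Cyp6w1, a cytochrome P450 gene, had an r of 0.766 over the 37 lines of its main cluster (permutation p 1e-05, the smallest they can give, adjusted p 7.7e-04; rho 0.747, p 1e-05), 0.733 without the 2 farthest lines and 0.663 with pool differences removed. Cyp12c1 had 0.603 over 38 lines (permutation p 8.0e-05, adjusted p 0.0023; rho 0.672, p 1e-05), 0.560 without the 2 farthest and 0.583 with pool differences removed.

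For the other genes with the highest r, 1 or a few lines also stood far from the rest at both stages. Over all lines r was 0.964 for CG10646, 0.936 for Aef1, 0.934 for CtsK1 and 0.928 for GstT2. It was 0.924 for ken, 0.911 for CG9953 and 0.901 for CG17683. Without DGRP427 alone r for GstT2 was 0.846. Cyp12c1 had 0.901 over all lines and 0.780 without DGRP306 alone. For Cyp6w1 r was 0.879 over all lines and 0.855 without DGRP370 alone. The values that follow were computed over the remaining lines. CG10646 was high in DGRP158 alone, and r over the other 40 lines was 0.332 (permutation p 0.0361, adjusted p 0.142; rho 0.327, p 0.0401), 0.285 without the 2 farthest lines and 0.159 with pool differences removed. The transcription factor gene ken was high in DGRP357, and r was 0.0934 without that line (permutation p 0.565). Aef1 was high in DGRP703 (r 0.369 without it, adjusted p 0.0937). CtsK1 was low in DGRP832 (r 0.290 without it, adjusted p 0.206), and CG17683 was low in DGRP441 (r 0.313 without it, adjusted p 0.166). CG9953 was low in DGRP427, and its r of 0.501 without that line passed (permutation p 0.0011, adjusted p 0.0109). Sans was high in DGRP774, DGRP787, DGRP796, DGRP801 and DGRP879, and r over the other 36 lines was 0.276 (permutation p 0.103, adjusted p 0.258; rho 0.273, p 0.108). GstT2 was high in DGRP427 and low in DGRP142 and DGRP804, and r over the other 38 lines was 0.521 (permutation p 7.9e-04, adjusted p 0.0094; rho 0.491, p 0.0021), 0.416 without the 2 farthest and 0.279 with pool differences removed. The adjustment covered 153 relations within clusters.

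**Figure D3:**
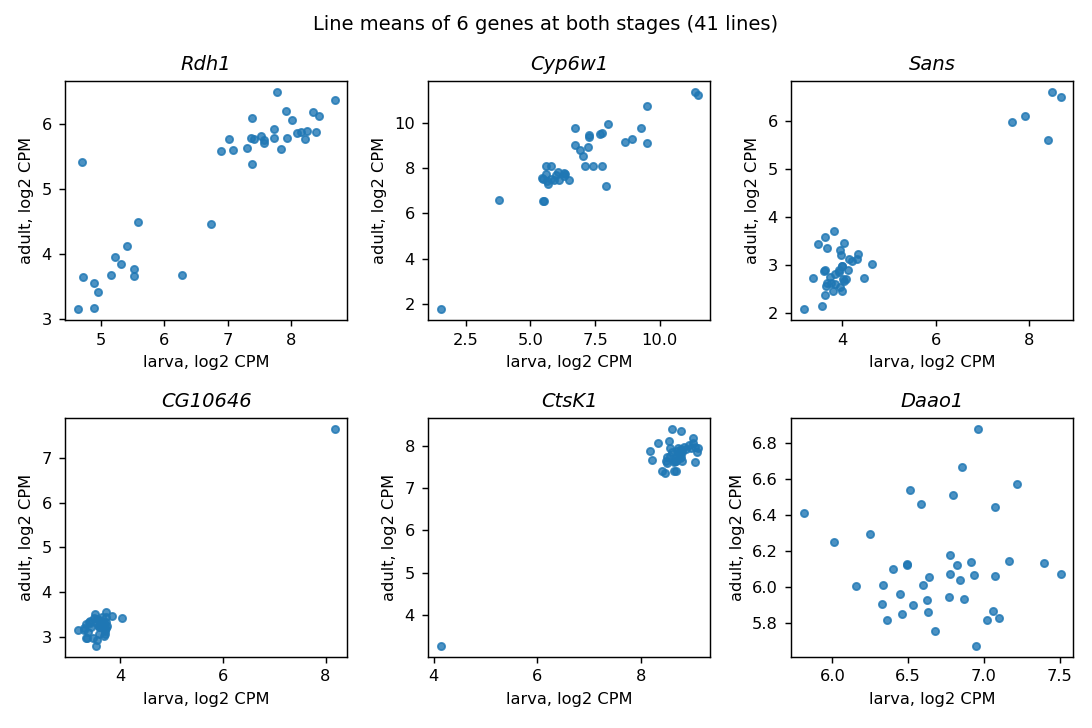
Each panel plots the larval (x axis) and adult (y axis) mean log2 CPM of 41 lines, 1 point per line, for 6 genes. Rdh1 shows groups of 26 and 12 lines and 3 lines outside them, Sans 5 lines apart, CG10646 and CtsK1 1 line apart, and Daao1 has an r of 0.129 over the 31 lines of its main cluster.

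Line means were correlated across stages for 1274 of 7414 genes at an adjusted p under 0.05, of which 1273 were positive. The median r over genes was 0.194 (95% interval 0.151 to 0.247), against -0.068 to 0.077 in 1000 joint permutations of the lines, and r was above 0 for 6216 genes. Among the 2849 genes with line variation at both stages, 965 were correlated and the median r was 0.320. Their median genetic correlation, which allows for replicate error, was 0.494 (0.460 to 0.602). It was at least 0.8 for 531 of them and under 0.2 for 543. By Spearman's rho 775 genes passed, 716 of them also by Pearson's r. With each gene's most influential line left out, 519 passed. That line was chosen as the one whose removal lowered the absolute r most, so fewer calls follow by construction. The negative gene, Atg14, an autophagy gene chosen after its values were seen, had an r of -0.408 (permutation p 0.0083, adjusted p 0.0487; rho -0.449, p 0.0039) and -0.457 without the 2 farthest lines. With pool differences removed its r was -0.367 and its adjusted p 0.0891, and without DGRP787 its r was -0.337 and its adjusted p 0.229. Over the 32 lines of its main cluster r was -0.409 (permutation p 0.02, adjusted p 0.0937). Among the 153 relations within clusters, the negative one that passed was that of the chaperone gene Hsc70-4, with an r of -0.567 over 27 lines (permutation p 0.0024, adjusted p 0.02; rho -0.548, p 0.0035), -0.527 without the 2 farthest lines and -0.695 with pool differences removed. Line variation of Hsc70-4 did not pass at either stage (adjusted p 0.199 in larvae and 0.366 in adults), and 14 lines lay outside the cluster.

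Other genes with strong line differences had an r near 0 over all lines. Daao1, a D-amino acid oxidase gene, had a heritability of 0.757 ± 0.079 in larvae and 0.733 ± 0.075 in adults. Over the 31 lines of its main cluster r was 0.129 (permutation p 0.486, adjusted p 0.689; rho 0.169, p 0.362), -0.012 without the 2 farthest lines and 0.247 with pool differences removed. CG16762, CG5246, bbc, HisT, CG7194, Peritrophin-15a and Acsx4 were the others nearest 0, with heritabilities from 0.616 to 0.897. For CG5246, r over the 32 lines of its main cluster was 0.396 (permutation p 0.0255, adjusted p 0.111). CG7194 had 0.324 over 32 lines (permutation p 0.0706) and -0.935 over 6 others (permutation p 0.0092, adjusted p 0.0521), and CG16762 had -0.139, 0.227 and -0.741 in clusters of 19, 11 and 7 lines. Peritrophin-15a had 0.263 over 23 lines and 0.416 over 15 (0.713 without the 2 farthest), and none of the relations within clusters of these genes passed the adjustment. The lowest r among genes variable at both stages belonged to MFS3, twin, Agpat2, jp and CG1468, none of which passed the adjustment over all genes. For MFS3, a transporter gene, r over 37 lines was -0.348 (permutation p 0.0359, adjusted p 0.142; rho -0.376, p 0.0226), -0.354 without the 2 farthest and -0.363 with pool differences removed. For twin, a deadenylase gene, r was 0.0676 without DGRP239. For Agpat2, r over the 36 lines of its main cluster was -0.256 (permutation p 0.133), and over all lines with pool differences removed its adjusted p was 0.0385. The line-by-stage interaction passed for 3199 genes, including 2195 of the 2849 variable at both stages and 572 of the 1274 correlated genes.

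Genes of detoxification carried line differences across stages more than other genes. Among 19 glutathione S-transferase genes the median r was 0.603, 0.410 above other genes (95% interval 0.211 to 0.492), and 14 were correlated (14 adjusted over the list alone). With Spearman's rho that difference was 0.199 (0.101 to 0.319). The 18 UDP-glycosyltransferase genes had a median of 0.531, higher by 0.337 (0.190 to 0.476), with 11 correlated (11 adjusted over the list alone). The 53 cytochrome P450 genes had a median of 0.472, higher by 0.280 (0.208 to 0.384), with 32 correlated (38 adjusted over the list alone). The DDT-resistance gene Cyp6g1 had an r of 0.516 over 39 lines (permutation p 8.4e-04, adjusted p 0.0094; rho 0.539, p 4.4e-04), 0.551 without the 2 farthest and 0.449 with pool differences removed, and DGRP356 and DGRP486 lay apart on the low side. GstE12 had 0.509 over 39 lines (permutation p 8.6e-04, adjusted p 0.0094; rho 0.489, p 0.0019), 0.393 without the 2 farthest and 0.438 with pool differences removed. For Cyp4g1, r over the 31 lines of its main cluster was -0.047 (permutation p 0.802). Cyp28a5 passed with 0.557 over 35 lines (adjusted permutation p 0.00598). GstS1 with -0.206 over 35 lines and GstT4 with 0.229 over 40 did not (adjusted p 0.428 and 0.349). Ugt37D1 passed with 0.454 over 38 lines (adjusted p 0.0281). Ugt37A2 with 0.457 over 32 lines and Ugt35C1 with 0.199 over 33 did not (adjusted p 0.0504 and 0.471). Over all lines r was 0.887 for Cyp6g1, 0.628 for GstE12, 0.762 for GstT4 and 0.13 for GstS1. The adjusted bootstrap p was 0.0087 for each family. Among genes variable at both stages, the differences in median r were 0.308 for glutathione S-transferases (0.153 to 0.402) and 0.236 for UDP-glycosyltransferases (0.097 to 0.377). For P450s the difference was 0.230 (0.142 to 0.294). The median genetic correlations of such members were 0.847, 0.718 and 0.654, against 0.494 over all genes variable at both stages. Against random lists matched on expression level and heritability, the median stood at percentile 99.65 for glutathione S-transferases, 84.3 for UDP-glycosyltransferases and 60.6 for P450s. With Spearman's rho the order was otherwise, with percentiles of 82.8, 99.98 and 98.5. With r the adjusted p against these random lists was 0.0624, 0.597 and 0.865 in the same order, so no family passed. Random lists also do not keep the co-expression of members.

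Digestive serine proteases had a median r of 0.368, higher than other genes by 0.174 (0.060 to 0.282), with 7 of 19 correlated (11 adjusted over the list alone) and an adjusted bootstrap p of 0.013. Carbohydrate digestion genes had a median of 0.408, higher by 0.214 (0.0049 to 0.330), with 5 of 10 correlated (7 adjusted over the list alone), an adjusted bootstrap p of 0.182 and an interval that included 0 under 4 alternatives. Both lists are of high heritability, with adult medians of 0.725 and 0.795, and stood at percentiles 39.4 and 9.67 of matched lists. Among genes variable at both stages, the differences were 0.058 (-0.052 to 0.171) and 0.092 (-0.073 to 0.234).

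DNA replication and cell cycle genes had a median r of 0.040, a difference from other genes of -0.156 (-0.274 to -0.021), with 1 of 31 correlated (0 adjusted over the list alone). This difference did not pass over the lists (adjusted bootstrap p 0.0988). The adjusted p against matched lists was 0.0026, but random lists do not keep the co-expression of members. Muscle sarcomere genes had a median r of -0.018 with 1 of 22 correlated (1 adjusted over the list alone), a difference of -0.213 whose interval of -0.402 to 0.037 includes 0, and an adjusted p of 0.0026 against matched lists. For the other 19 lists the interval of the difference included 0, from oxidative phosphorylation at -0.131 (-0.322 to 0.070) to immune recognition at 0.134 (-0.0059 to 0.230). For immune recognition the interval excluded 0 with pool differences removed (0.123, 0.0016 to 0.232), without the 3 larval libraries that matched other lines (0.124, 0.0064 to 0.228) and with all 164 columns (0.130, 0.0043 to 0.237).

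**Figure D4:**
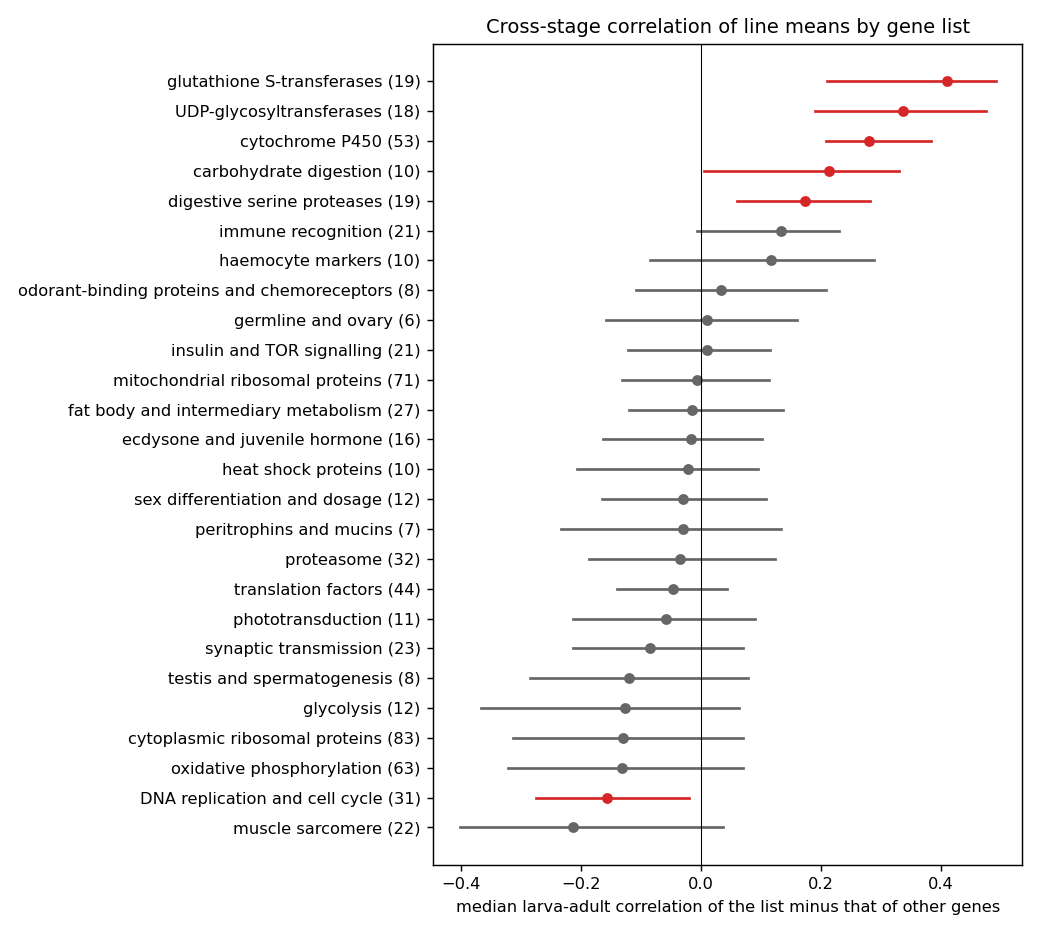
For each of 26 gene lists, with the number of members in brackets, the point is the median larva-adult correlation of line means minus that of all other genes, and the line is its 95% bootstrap interval over 41 lines. The 6 lists in red have intervals that exclude 0, with glutathione S-transferases highest at 0.410 by Pearson's r (0.199 by Spearman's rho, below UDP-glycosyltransferases at 0.362 and P450s at 0.237) and DNA replication and cell cycle genes below 0 at -0.156.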

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

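Tests chosen after the result was seen were the splits of libraries, the 3 tests of weak carry-over, the matched lists for each detoxification family, all values with rho, and the tests of the side and number of lines standing apart.

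Line differences changed between larvae and adults for 3199 genes by the edgeR line-by-stage interaction, with the Benjamini-Hochberg adjustment. Among named genes with high r, the interaction had an adjusted p of 1.5e-07 for Sans, 6.7e-04 for Rdh1, 0.0014 for Aef1, 0.0014 for Cyp12c1, 0.012 for CtsK1 and 0.026 for CG9953. Among those with the lowest r it was 2.4e-06 for MFS3, 9.2e-07 for twin, 4.2e-06 for Agpat2, 8.0e-04 for jp and 3.3e-05 for CG1468. Among those with r nearest 0, which were named partly for their interaction, it was 1.7e-09 for CG16762, 4.6e-08 for CG5246, 2.5e-07 for bbc, 4.4e-10 for HisT, 1.5e-14 for CG7194, 3.3e-11 for Daao1, 5.5e-11 for Peritrophin-15a and 4.4e-10 for Acsx4.

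For the stage comparison, chance assignment of single libraries can be excluded. In limma-trend the real split called 6869 genes, and 1 of 100 splits of the libraries, the real split itself, called as many. The highest of the other splits called 3946. Those splits mixed both stages and ignored sequencing pools, which lie within stage, so they cannot tell stage from pool.

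Line differences carried over weakly from larva to adult, with a median r of 0.194 over all 7414 genes. Over the 2849 genes with line variation at both stages the median r was 0.320. In those genes replicate noise alone would give a genetic correlation near 1, and its median was 0.494 with an upper bound of 0.602. This argues against replicate noise as the whole cause. Without the 3 larval libraries that matched other lines the median r was 0.206, within the interval of 0.151 to 0.247. Those libraries were thus not the whole cause. With pool differences removed the median r was 0.190, also within that interval. That removal had no line term and could take line differences with it, so it cannot decide on pools. No biological explanation was tested.

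Detoxification families carried over more than other genes, with a median r of 0.526 over 90 genes against 0.192. Reads shared between neighbouring paralogs would leave no excess in members without a family neighbour within 20000 bp, but for these 37 genes the difference was 0.203 (0.105 to 0.291) and 0.127 with rho (0.0501 to 0.234), lower than for the 53 others by an amount whose interval of -0.301 to -0.0868 excludes 0. Expression level and heritability stay open for each family, since r and rho differ against lists matched on them: P450s stood at percentile 60.6 with r and 98.5 with rho, UDP-glycosyltransferases at 84.3 and 99.98, and glutathione S-transferases at 99.65 and 82.8. The 3 families together stood at 99.13 with r, 97.61 with the cyclophilins Cyp1 and Cyp40 left in, and 99.75 with rho. Alleles that map poorly to the reference could not be excluded, since the median skewness of line means over 57 correlated members was -0.428 (-0.547 to -0.0412), and no biological explanation was tested.

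In 103 genes the same line stood at least 1 log2 unit from the nearest other line, on the same side, at both stages, as DGRP805 did on the high side for CG15784, a gene chosen after its values were seen. Permutations of the lines gave at most 18 such genes, so chance agreement between stages is excluded. Contamination of a line at both stages would concentrate them, but the 3 lines with most held 17.5% and 35 lines held at least 1. A wrong label at 1 stage would instead break the agreement between stages, so this spread cannot weigh mislabelling. Poor mapping of alleles to the reference would place the line on the low side, but 40.8% had it on the high side. Every gene of the table had at least 11 counts in every library, so genes nearly lost in 1 line are absent. Their absence can raise the high-side share, so that share cannot size the part of poor mapping. It stays open for the 61 genes on the low side. No biological explanation was tested.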

How the results depend on the processing

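Tests added after the data were seen were those with pools as replicates, with all 164 columns, without 3 larval libraries, with roX1, with a filter of 5 CPM for line variation, of fold in DESeq2, without the most influential line, with the cyclophilins, with rho in the matched lists and within clusters. The differences in median r changed sign under at least 1 alternative, with intervals that included 0 before and after, for the cytoplasmic ribosomal (-0.130, and 0.155 among genes variable at both stages), mitochondrial ribosomal, translation factor, odorant-binding, germline, heat shock, ecdysone, synaptic, proteasome, fat body and insulin lists. Genes differing between lines in larvae fell to 2288 with pool number as a factor. Gene lists differing between stages fell to 0 with an estimated correlation in camera, where 3 had an unadjusted p under 0.05. Correlated genes fell to 775 with Spearman's rho, to between 633 and 804 without 1 replicate of each line, and to 519 without each gene's most influential line. That line was the one whose removal lowered the absolute r most, so the fall to 519 follows in part by construction. Without 1 replicate the median r lay between 0.142 and 0.167, and fewer replicates per line mean lower it by construction. The median adult heritability was 0.45 with roX1 as a covariate. For the other changes the cause was not tested. The other 88 values of these and the remaining counts and medians lay within 1.5 times the main count or within its spread. Of the values for named genes and lists, 694 kept their side of the threshold, 18 lost it and 4 gained it. The no-filter alternative removes nothing, and the planned sex covariate and line tests without 1 replicate were not run. Replicate numbers did not pair larval with adult samples.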

Other observations

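The X-linked tests, the list tests and the values with rho were chosen after the data were seen, and the test of carry-over against the stage difference was chosen before.

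Line variation passed for more genes in adults than in larvae in the muscle and oxidative phosphorylation lists. Muscle sarcomere genes, which encode the contractile apparatus, had a median heritability of 0.178 in larvae and 0.530 in adults, a difference of 0.352 (95% interval 0.0494 to 0.663, 22 genes), and line variation passed for 3 of them in larvae and 21 in adults. Oxidative phosphorylation genes had 0.0850 in larvae and 0.394 in adults, a difference of 0.309 (0.0385 to 0.595, 63 genes), with 8 and 52 passing. Beyond the difference of other genes, the intervals were -0.0484 to 0.564 and -0.0346 to 0.480, which include 0. Without adjustment over the 26 lists, the difference also excluded 0 for glutathione S-transferases (0.196, 0.0488 to 0.409), UDP-glycosyltransferases (0.139, 0.0079 to 0.281) and peritrophins and mucins (0.107, 0.0012 to 0.384). For 11 phototransduction genes it was -0.180 (-0.322 to 0.127), which includes 0, and relative to other genes -0.284 (-0.378 to -0.0164).

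The correlation of line means across stages was lower for X-linked than for autosomal genes. Heritability was not compared between these groups, so lower carry-over cannot be told from larger replicate error. The median r was 0.151 over 1227 X-linked genes and 0.204 over 6110 autosomal genes, a difference of -0.0530 (-0.0814 to -0.0280), and of -0.0537 with rho (-0.0792 to -0.0272). roX1, which marks the male share of a sample, had a heritability of 0.096 in larvae and 0.104 in adults.

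A hypothesis was that genes that differ more between stages carry line differences over less. Among genes variable at both stages, the 713 genes with the largest absolute fold change between stages had a median r of 0.293, and the 713 with the smallest had 0.339. The difference of -0.0460 (-0.0731 to -0.0045) excludes 0, but with rho it was -0.0155 (-0.0580 to 0.0130), which includes 0, so the hypothesis stays open. The genetic correlations were 0.434 and 0.514, a difference of -0.0800 (-0.144 to -0.0300).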
